A study of Homo sapiens with 10 samples.

How the data were processed

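The histone mark H3K4me1, which lies at enhancers and along the flanks of active promoters, was profiled by CUT&Tag in human macrophages. CUT&Tag is an antibody-directed tagmentation assay whose reads pile up where the mark is. Per the labels' protocols, blood monocytes were matured with macrophage colony-stimulating factor for 7 days and then stimulated for 8 h. The groups received lipopolysaccharide (LPS, a TLR4 ligand) at 100 ng/mL, Pam3CSK4 (a TLR2 ligand) at 100 ng/mL, interferon-beta at 10 U/mL, interferon-gamma at 100 ng/mL, or nothing. Each of the 5 groups has 2 libraries, 10 in all. Nothing in the labels says whether the replicates of a group are separate donors or separate cultures, so the p-values measure a spread between libraries that may be technical.

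The deposited table holds log2 values per region and library, named as log2 RPKM by its authors. Per the submitters' processing notes, Bowtie2 2.2.5, SAMtools 1.9, Picard, MACS3 3.0.0b1 and featureCounts were used with build hg38. The order of the steps, how the regions were defined and merged, and any filter are not given in the sources used here. From the values themselves, each one is log2(RPKM + 0.98). The 0.98 is read from the values and is stated nowhere. RPKM here is reads per kilobase of region, with length taken as end minus start and scaled to a common number of reads in the regions of the table. Turned back, the values are CPM with 2 decimals that have the same sum in each library, to within rounding. Their steps are whole reads, and between 99.9% and 100% of a library's values lie within 0.0051 CPM of a whole number of reads. Reads per region and depth were recovered in this way. Region starts and ends are printed as the deposited table gives them, which does not say whether starts count from 0 or 1.

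The table has 92650 regions, of a median width of 579 bp (170 to 5796 bp), and none overlaps another. The 8 mitochondrial regions and 103 regions on alternate or unplaced contigs were left out, which leaves 92539 tested regions. No region was left out for low signal. Recovered depth in the regions was 9018491 and 4662385 reads in the unstimulated libraries (replicates 1 and 2), 14645954 and 28034502 with LPS, 4788800 and 3632078 with Pam3CSK4, 18186432 and 7112564 with interferon-beta, and 14311819 and 11050611 with interferon-gamma. Intervals and lower bounds that rest on reads cover counting error only, since CUT&Tag reads without molecular identifiers are not independent molecules.

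Groups were compared with limma 3.58.1 in R 4.3.3, on the log2 values as deposited. A group-means model of all 10 libraries was used, with moderated variances that follow a trend with the mean, and a Benjamini-Hochberg adjusted p under 0.05 within each comparison. A region past that threshold is said to have risen or fallen. The 7 comparisons are each stimulus against unstimulated cells, LPS against Pam3CSK4, interferon-gamma against interferon-beta, and LPS against interferon-beta. Every adjusted p of a region comes from limma. Errors printed after ± are limma standard errors of the log2 fold change, with n = 2 libraries per group. Tables were prepared and plots drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

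The fit was tested on simulated data: counts were drawn for the 92539 regions at the real depths and spreads, with 200 regions changed. Changes of 4-fold were recovered in 65% of regions for LPS, 71% for Pam3CSK4, 66.5% for interferon-beta and 68.5% for interferon-gamma against unstimulated cells. The recovery at 4-fold was 69% for LPS against Pam3CSK4, 77% for interferon-gamma against interferon-beta and 69% for LPS against interferon-beta. Rises of 4-fold were recovered more often (78% to 88%) than falls (52% to 66%), so the splits of higher and lower regions are tilted towards rises. False calls at 4-fold numbered 7, 42, 6 and 8 for the 4 stimuli in that order and 17, 0 and 2 for the direct comparisons. Beside the regions recovered, this is far over 5% of the calls for Pam3CSK4 and for LPS against Pam3CSK4, and slightly over 5% for LPS and interferon-gamma. With Pam3CSK4 there were also 4 false calls at 1.5-fold and 3 at 2-fold. Changes of 2-fold were recovered in 0% to 1.5% of regions and changes of 1.5-fold in 0%, so a region that did not pass may still have changed by that much. These shares hold for 200 changed regions. Where more regions change, the adjusted p is less strict and recovery may be higher. With LPS, 2395 of the 3157 rises in the real data were at least 2-fold, and the others were smaller.

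Each region was assigned to the protein-coding gene whose annotated span (GRCh38.p14) is nearest to its centre, within 100 kb. That gave a gene to 86182 regions (93.1%). This departs from the plan, which called for the nearest transcription start site, because the annotation used here has no strand. A region counts as distal when its centre lies over 1 kb from both ends of every annotated gene. An assignment by distance does not show that a region regulates that gene. Where genes overlap, the assignment is uncertain: the span annotated for LIPA covers the IFIT genes, so regions between those genes are assigned to LIPA. Such regions are not counted in the list of type I interferon response genes.

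The design, the alternatives and the choice of genes were fixed before the data were examined. Named regions follow this rule. For each comparison, part (a) takes the 12 largest rises and part (b) the 6 largest falls past the threshold in which both libraries of a group lie above both of the other, 1 region per gene. Part (c) takes, for each stimulus and gene list, the 3 regions with the smallest p, 1 per gene. Part (d) takes, for 14 genes (among them IFIT1, MX1, ISG15, CXCL10, GBP5, IRF1, TNF, IL6, CXCL8, IL1B, CCL5, CSF1R and ACTB), the region nearest to an end of the gene, whatever its value. A selection from these is printed. TNF and CCL5 have no region within 100 kb and so no value. Regions named outside this rule are said to have been chosen after their values were seen.

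The 15 gene lists cover type I interferon response genes, interferon-gamma response genes, MHC class I presentation genes, NF-kB and TLR inflammatory genes, immediate early genes, resident macrophage identity genes, sterol and lipid handling genes, interferon receptors and STATs, housekeeping genes, and markers of T and NK cells, B cells, neutrophils, dendritic cells, platelets and erythroid cells, and non-blood tissues. They were written from general knowledge. Each list was tested with limma's camera on the regions assigned to its genes, with a preset correlation of 0.01, and adjusted over the 105 tests of 15 lists in 7 comparisons. The adjusted p with an estimated correlation is given beside it. With the preset, 14 of the 105 tests passed, and 0 passed with an estimated correlation. A list said to have passed, moved up or been higher did so with the preset only. The estimated correlation was 0.0439 for the NF-kB list, 0.0564 for the interferon-gamma list and 0.0311 for the receptor list, all over the preset. It was 0.00686 for the type I list, under the preset. With LPS the unadjusted camera p of that list still went from 5.75e-05 to 0.00679. A larger correlation therefore does not account for its loss, and the cause was not tested. Neighbouring regions of a gene are not independent, so the p-values with the preset may be too small. Among the 14, the median, the mean and the test had the same sign.

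A de novo region is one that rose by a log2 of at least 1 and whose mean in unstimulated cells lies under the median of all tested regions. It is a description with no test of its own. The share of distal regions among those that rose was compared with all other regions by two-sided Fisher's exact test. The overlap of rises between stimuli is also given beside that of independent lists. The overlap, and the correlation and covariance of the fold changes, are given beside those of 20 simulations of unchanged groups set against the same 2 unstimulated libraries. Where a group has 0 reads in a region, a bound is computed against 3 reads over the group and written as "at least". Where it has 1 to 3 reads, the ratio of depth-scaled reads is given with its exact 95% interval.

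The alternatives were median centring and quantile normalization, a constant of 1 in the logarithm, leaving out the lowest 25% of regions, fitting only the 2 groups compared, the replicate number as a block, a robust variance prior, library weights, and leaving out each of the 10 libraries in turn. Lists were also tested within 20 kb, distal regions beyond 5 kb, and de novo regions with a baseline in the lowest 25%. Thinning every library to the reads of the shallowest one (the median of 5 draws) and voom from limma on the recovered reads were added after the data were seen. No genome sequence was used here, so the planned tests of 10 sequence motifs and the correction for GC content were not run.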

Results

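H3K4me1 was measured in 92539 genomic regions (build hg38) of human monocyte-derived macrophages that were left unstimulated or stimulated for 8 h with LPS, Pam3CSK4, interferon-beta or interferon-gamma, with 2 libraries in each of the 5 groups. The depth of the libraries ran from 3632078 reads in the regions (Pam3CSK4 replicate 2) to 28034502 (LPS replicate 2), with a median of 18 to 133 reads per region. Replicates of a group correlated across regions with r from 0.843 (Pam3CSK4) to 0.932 (interferon-gamma). Fold changes are log2, and a region rose or fell only where its limma adjusted p was under 0.05. The series asks which enhancers arise when IRF1 acts with the interferon-activated factors ISGF3 or GAF.

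The comparison of LPS with unstimulated cells asks what a TLR4 ligand adds to or removes from the enhancer landscape. LPS raised H3K4me1 beside interferon-induced genes and beside genes of the inflammatory response. The region 0.123 kb from CXCL10, a chemokine that draws T cells (chromosome 4, 76023439 to 76023802), rose by 2.31 ± 0.28 (adjusted p = 0.00044), from a mean of 2.67 to 4.98 on the scale log2(RPKM + 0.98). A region 1.72 kb from GBP5, an interferon-induced GTPase that promotes inflammasome activity (chromosome 1, 89274300 to 89274857), rose by 2.43 ± 0.25 (adjusted p = 0.000148). CD80, a costimulatory ligand for T cells, had a region 3.13 kb away that rose by 1.58 ± 0.15 (adjusted p = 8.88e-05), and SERPINB2, an inhibitor of plasminogen activators that is strongly induced in activated macrophages, had one 0.135 kb away that rose by 2.18 ± 0.28 (adjusted p = 0.000636).

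Other regions near interferon-stimulated genes rose with LPS. SOCS1, a feedback inhibitor of JAK kinases, gained 2.06 ± 0.25 at a region 2.91 kb away (adjusted p = 0.000387). ISG15, a ubiquitin-like antiviral modifier, gained 2.07 ± 0.23 at a region 4.13 kb away (adjusted p = 0.000267) and 1.54 ± 0.23 at the region nearest to its end (adjusted p = 0.00194). Another region of ISG15, 0.546 kb away and chosen after its values were seen, fell by 1.76 (adjusted p = 0.00424). A region inside HERC6, a member of the family of ligases that attach ISG15, rose by 3.07 ± 0.42 (adjusted p = 0.000942). One inside the exonuclease gene ISG20 rose by 1.84 (adjusted p = 0.000811), and one inside IRF2, a regulator that competes with IRF1 for its sites, by 2.36 (adjusted p = 0.000606). The region nearest to IFIT1, which binds viral RNA, rose by 1.56 (adjusted p = 0.0196). The largest rises lay in regions nearly empty in unstimulated cells. A region inside IDO2, a tryptophan-degrading enzyme, rose by 4.35 ± 0.51, with 441 reads against 7, and one near SLAMF6, a receptor of lymphocytes, by 3.37. Regions with 0 reads in unstimulated cells were at least 34.2-fold higher inside JMJD1C and at least 20.9-fold higher inside KDM4C, both of the family of histone demethylases. Near FASLG, the gene of a death-receptor ligand, depth-scaled reads were 32.4 times those in unstimulated cells, which had 2 reads (95% interval 8.85 to 269).

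LPS also lowered the mark at immune genes. A region inside SOD2, a mitochondrial superoxide dismutase and NF-kB target (chromosome 6, 159689026 to 159689303), fell by 2.57 ± 0.33 (adjusted p = 0.000569). One inside WARS1, a tryptophanyl-tRNA synthetase induced by interferon-gamma, fell by 1.91 ± 0.21 (adjusted p = 0.000245). Regions at IFI44L, an interferon-induced gene, and at IFNGR1, the ligand-binding chain of the interferon-gamma receptor, fell by 2.41 (adjusted p = 0.0043) and 1.02 (adjusted p = 0.0033). A region inside NLRC5, which activates MHC class I genes, fell by 1.58 (adjusted p = 0.0475). Regions near the immediate early genes DUSP1, KLF6 and ATF3 rose by 1.38, 1.79 and 1.58. Among macrophage identity genes, a region inside the scavenger receptor gene STAB1 rose by 1.56 and one inside MS4A4A by 1.54. CH25H, which makes an antiviral oxysterol, gained 1.43 at a region 41.7 kb away, and the lipid regulator PPARG gained 1.48 inside the gene. The regions nearest to MX1 (0.30, adjusted p = 0.32), IRF1 (-0.08, adjusted p = 0.8), IL6 (0.52, adjusted p = 0.141), CXCL8 (0.12, adjusted p = 0.9), IL1B (-0.02, adjusted p = 0.988), CSF1R (-0.32, adjusted p = 0.225) and ACTB (-0.27, adjusted p = 0.474) did not pass. A region inside MX1, chosen after its values were seen, rose by 1.29 (adjusted p = 0.00348).

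In all, 4168 regions passed with LPS, 3157 higher and 1011 lower. The count was 299 without LPS replicate 2, 1411 without unstimulated replicate 2, and 6652 and 6718 without Pam3CSK4 replicates 1 and 2. With every library thinned to the shallowest, it was 1959. The excess of rises varied: 4866 were higher and 4426 lower with voom, 2563 and 1577 without LPS replicate 1, and 1283 and 128 without unstimulated replicate 2. Of 40 such regions examined by name, 36 stayed past the threshold without LPS replicate 1, 18 without LPS replicate 2, 34 without unstimulated replicate 1 and 30 without unstimulated replicate 2. The regions given for CXCL10, CD80, SERPINB2, SOCS1, HERC6, ISG20, IRF2, IDO2, SLAMF6, JMJD1C, KDM4C, DUSP1, SOD2 and WARS1, and the larger rises at GBP5 and ISG15, passed without any 1 of the 10 libraries. Without LPS replicate 2 the regions of KLF6, ATF3, MS4A4A, STAB1, CH25H, PPARG, FASLG, IFNGR1, IFI44L and IFIT1 and the region nearest to ISG15 did not pass. Those of STAB1, PPARG, IFI44L and IFIT1 did not pass without unstimulated replicate 2, nor that of IFIT1 without unstimulated replicate 1, and that of NLRC5 passed only with all libraries or without 1 of the Pam3CSK4 libraries.

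**Figure D1:**
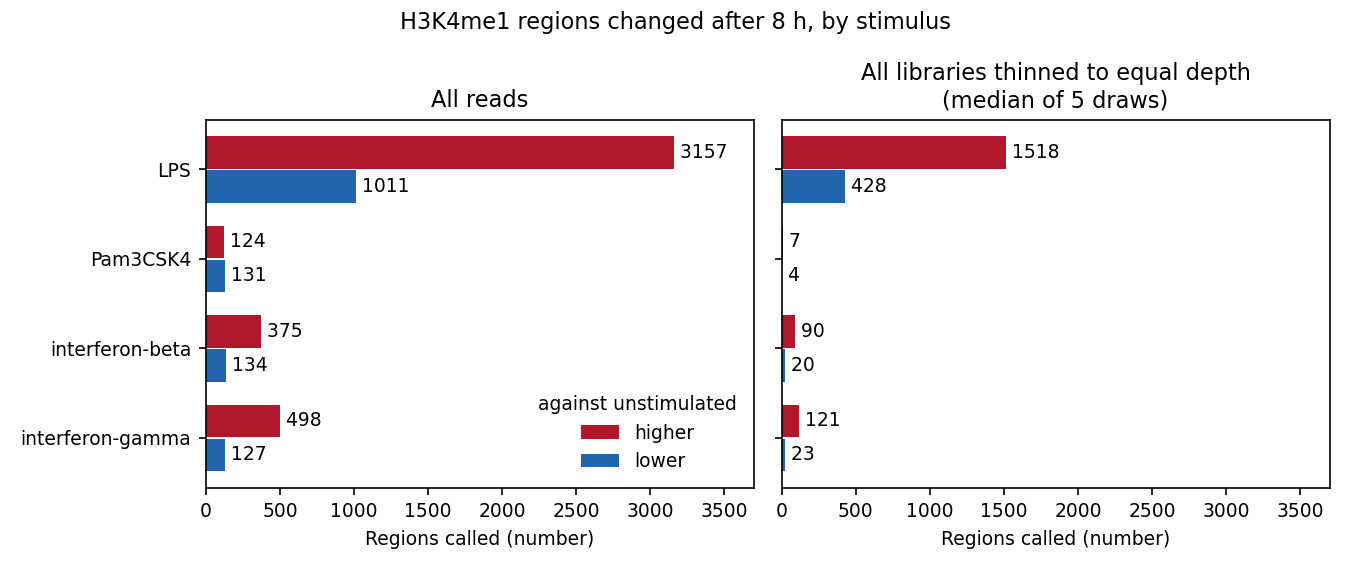
Number of regions past adjusted p 0.05 against unstimulated cells (horizontal axis, regions) for each stimulus (vertical axis), higher and lower drawn as separate bars. All reads are on the left, and every library thinned to the depth of the shallowest is on the right (median of 5 draws). With all reads the bars for LPS reach 3157 and 1011 regions, and after thinning 1518 and 428, beyond those of the other 3 stimuli.

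NF-kB and TLR inflammatory genes moved up as a list with LPS, with 50 regions higher and 10 lower of 461 (camera adjusted p = 9.5e-06). The adjusted p = 0.503 with an estimated correlation, and adjusted over the list alone 85 were higher and 18 lower. Type I interferon response genes held movements in both directions, with 22 regions of 17 genes higher and 12 regions of 7 genes lower of 131 (adjusted p = 0.00101). The adjusted p = 0.417 with an estimated correlation, and adjusted over the list alone 35 were higher and 18 lower. Interferon-gamma response genes had 27 higher and 10 lower of 136 (adjusted p = 0.00132, and 0.629 with an estimated correlation), and adjusted over the list alone 39 and 15. Interferon receptors and STATs had 22 higher and 5 lower of 281 (adjusted p = 0.0367, and 0.719 with an estimated correlation), and adjusted over the list alone 33 and 12. Without LPS replicate 2 these 4 lists had 3 higher and 2 lower, 4 and 1, 3 and 4, and 1 and 0, in that order. Without unstimulated replicate 2 they had 22 and 3, 13 and 5, 10 and 6, and 9 and 1, and without unstimulated replicate 1, 42 and 4, 13 and 10, 14 and 5, and 20 and 3. The type I list had 12 and 8 without LPS replicate 1, and the NF-kB list 70 and 16 without Pam3CSK4 replicate 2. The receptor list had 14 and 4 without interferon-beta replicate 1 and 14 and 5 without either interferon-gamma library. The adjusted p of the interferon-gamma list was 0.174 without LPS replicate 2, and that of the receptor list was 0.611 without LPS replicate 2, 0.196 without unstimulated replicate 2 and 0.0916 with regions within 20 kb only.

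The other lists did not pass with LPS: MHC class I presentation genes (adjusted p = 0.616, 8 of 17 genes with a region), immediate early genes (0.18, with 20 regions higher and 5 lower), resident macrophage identity genes (0.954, 10 and 7), sterol and lipid handling genes (0.87, 3 and 0), housekeeping genes (0.842, 3 and 0), and markers of T and NK cells (0.388), B cells (0.971), neutrophils (0.993), dendritic cells (0.546), platelets and erythroid cells (0.993) and non-blood tissues (0.147). With an estimated correlation their adjusted p lay between 0.417 and 0.998. Median, mean and test differed in sign for the housekeeping, neutrophil, and platelet and erythroid lists. None of these 11 lists passed in any other comparison.

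The comparison of Pam3CSK4 with unstimulated cells asks what a TLR2 ligand, which signals without the interferon-inducing adaptor TRIF, does to the mark. Pam3CSK4 raised it at regions of some inflammatory genes. None of the 131 regions of the type I interferon list passed. Of all other regions only 0.134% rose and 0.142% fell, so a list of that size may hold none, and the 0 says little about these genes. A region inside MAPKAPK2, a kinase that stabilises cytokine messages downstream of p38 (chromosome 1, 206732880 to 206733592), rose by 2.83 ± 0.22 (adjusted p = 8.78e-05), and one inside COX17, a mitochondrial copper chaperone, by 2.89 ± 0.28 (adjusted p = 0.00111). The same regions as with LPS rose near SERPINB2 (1.87 ± 0.28, adjusted p = 0.0215) and CD80 (0.99 ± 0.15, adjusted p = 0.0215), and the same region inside SOD2 fell by 2.67 ± 0.33 (adjusted p = 0.00716). A region inside CSF1R, the receptor that sustains macrophages, fell by 1.66 ± 0.28 (adjusted p = 0.0302), while the region nearest to an end of CSF1R did not pass (0.04, adjusted p = 0.93).

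Further rises with Pam3CSK4 lay near CCR2, a receptor that brings monocytes out of the blood (2.59, adjusted p = 0.0157), and ALOX12B, a lipoxygenase (2.81, adjusted p = 0.0196). Regions near SOCS1, at 19.2 kb, and SOCS3, at 19.2 kb, both feedback inhibitors of cytokine signals, rose by 1.02 (adjusted p = 0.0391) and 0.78 (adjusted p = 0.03). Regions of the transcription factor gene STAT4 and the kinase gene JAK1 rose by 1.27 (adjusted p = 0.0365) and 1.04 (adjusted p = 0.0386). DUSP1, a phosphatase that ends MAP kinase signals, gained 0.92 (adjusted p = 0.0385). The region inside RASSF6, with 0 reads in unstimulated cells, was at least 9.21-fold higher. With 0 reads in Pam3CSK4 cells, a region inside PHACTR1, an actin regulator of vascular cells, was at least 6.98-fold lower, and one inside the endocytosis gene FCHO2 at least 4.72-fold lower. Near GASK1B, depth-scaled reads in unstimulated cells were 12.6 times those with Pam3CSK4, which had 2 reads (95% interval 3.28 to 108). Near INSIG1, a brake on sterol synthesis, they were 6.98 times those with Pam3CSK4, which had 3 reads (2.19 to 35.5). Regions of the following interferon-induced genes did not pass: CXCL10 (-0.19, adjusted p = 0.825), ISG15 at its nearest region (-0.40, adjusted p = 0.491) and at the region 4.13 kb away (0.94, adjusted p = 0.103), GBP5 (0.73, adjusted p = 0.289), MX1 (0.11, adjusted p = 0.826), IRF1 (0.14, adjusted p = 0.739) and IFIT1 (0.16, adjusted p = 0.893).

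In all, 255 regions passed with Pam3CSK4, 124 higher and 131 lower, and this count moved under the loss of each library. It was 434 and 9 without unstimulated replicates 1 and 2, 23 and 21 without LPS replicates 1 and 2, 2328 and 452 without Pam3CSK4 replicates 1 and 2, 50 and 53 without interferon-beta replicates 1 and 2, and 23 and 24 without interferon-gamma replicates 1 and 2. The split turned with 1 library: 567 were higher and 1761 lower without Pam3CSK4 replicate 1, 80 and 372 without replicate 2, 284 and 150 without unstimulated replicate 1, and 8 and 1 without unstimulated replicate 2. The count was 9 with voom and 0 with only the 2 groups in the fit. In simulated data of this comparison, 42 regions were called falsely beside 71% of the 200 changed ones. Of 20 such regions examined by name, 2 stayed past the threshold without unstimulated replicate 2, those of MAPKAPK2 and COX17, and 14 without unstimulated replicate 1. Without Pam3CSK4 replicates 1 and 2, 19 and 14 did. The regions of CCR2, PHACTR1 and SOD2 did not pass without unstimulated replicate 2. ALOX12B did not pass without that library or either LPS library, and SERPINB2, CD80 and RASSF6 did not pass without these or either interferon-gamma library. GASK1B, FCHO2, SOCS1, SOCS3, STAT4, JAK1, DUSP1, INSIG1 and CSF1R also did not pass without either interferon-beta library. Of these, SOCS1, STAT4, JAK1, DUSP1 and INSIG1 did not pass without unstimulated replicate 1. SOCS1, STAT4, DUSP1 and CSF1R did not pass without Pam3CSK4 replicate 2, and JAK1 did not without Pam3CSK4 replicate 1.

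NF-kB and TLR inflammatory genes moved up as a list with Pam3CSK4 (adjusted p = 2.95e-05, and 0.503 with an estimated correlation), with 9 regions higher and 3 lower. Adjusted over the list alone, 34 were higher and 5 lower. The counts over all regions were 0 and 0 without unstimulated replicate 2, 0 and 1 without any 1 of the LPS or interferon-gamma libraries, 19 and 8 without Pam3CSK4 replicate 1, 5 and 1 without Pam3CSK4 replicate 2, and 3 and 1 without either interferon-beta library. Interferon-gamma response genes passed with 1 region higher and 0 lower, that of SOCS1 (adjusted p = 0.0252, and 0.829 with an estimated correlation), and adjusted over the list alone 2 and 0. That adjusted p was 0.117 without unstimulated replicate 2, 0.134 without Pam3CSK4 replicate 1 and 0.0691 with regions within 20 kb only. The type I list did not pass (adjusted p = 0.616, and 0.868 with an estimated correlation), with 0 regions called by limma. Median, mean and test differed in sign for the B cell and neutrophil lists.

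The comparison of interferon-beta with unstimulated cells asks what the activator of ISGF3 does by itself. Interferon-beta lowered the mark inside several of its own target genes and raised it beside others. A region inside TNFSF10, the death ligand TRAIL (chromosome 3, 172520549 to 172520781), fell by 2.88 ± 0.32 (adjusted p = 0.00209). Regions inside IFIT2 and IFIT3, which act against viral translation, fell by 2.86 ± 0.39 (adjusted p = 0.00635) and 2.35 ± 0.40 (adjusted p = 0.0154). At ISG15 a region 0.546 kb from the gene (chromosome 1, 1014526 to 1015646) fell by 2.04 ± 0.31 (adjusted p = 0.00887), while another, 0.273 kb from it, rose by 1.13 ± 0.23 (adjusted p = 0.0426). The regions near GBP5 and SOCS1 that rose with LPS rose here by 1.84 ± 0.25 (adjusted p = 0.00635) and 1.75 ± 0.25 (adjusted p = 0.00711).

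The region nearest to CXCL10 rose by 1.39 (adjusted p = 0.0399). A region 5.92 kb from ACOD1, which makes itaconate, rose by 1.89 (adjusted p = 0.0135), and the region inside IRF2 by 1.55 (adjusted p = 0.0327). CH25H gained 1.42 (adjusted p = 0.0197), KLF6 1.38 (adjusted p = 0.0267), CD80 0.72 (adjusted p = 0.0438) and the cholesterol exporter gene ABCA1 0.70 (adjusted p = 0.0409). Large rises lay near SLAMF6 (3.02 ± 0.33, adjusted p = 0.00209), RBM45, a neural RNA-binding protein (3.00), and SNX6, a retromer component (3.00). Others lay near LINGO1, an inhibitor of myelination (2.99), ATG7, an enzyme of autophagy (2.85), the heart regulator NKX2-5 (2.73) and CPEB3, a regulator of translation (2.70). The region inside JMJD1C, with 0 reads in unstimulated cells, was at least 11.7-fold higher. SECTM1, an interferon-induced secreted protein, had a region inside the gene that fell by 1.22 (adjusted p = 0.0254). The regions nearest to MX1 (0.48, adjusted p = 0.228), IRF1 (0.20, adjusted p = 0.64), IFIT1 (1.29, adjusted p = 0.13) and GBP5 (1.14, adjusted p = 0.103) did not pass, nor did NLRC5 (-1.48, adjusted p = 0.153). A region inside MX1, chosen after its values were seen, rose by 1.22 (adjusted p = 0.0197).

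In all, 509 regions passed with interferon-beta, 375 higher and 134 lower. The split was 461 and 85 with median centring, 73 and 2 without unstimulated replicate 2 and 11 and 8 without interferon-beta replicate 1. The count was 75 without unstimulated replicate 2, 320 and 307 without LPS replicates 1 and 2, 1142 and 1139 without Pam3CSK4 replicates 1 and 2, 19 and 4 without interferon-beta replicates 1 and 2, and 214 and 188 without interferon-gamma replicates 1 and 2. Of 25 such regions examined by name, 17 and 5 stayed past the threshold without unstimulated replicates 1 and 2, and 4 and 1 without interferon-beta replicates 1 and 2. The fall at TNFSF10 passed without any 1 of the 10 libraries. The falls at IFIT2 and ISG15 did not pass without unstimulated replicate 2 or interferon-beta replicate 2. The fall at IFIT3 did not pass without either unstimulated library or without interferon-beta replicate 2. The fall at ISG15 and the rises at GBP5 and SOCS1 did not pass without interferon-beta replicate 1, nor did these rises without replicate 2. SLAMF6 did not pass without interferon-beta replicate 2, and every other rise given here did not pass without either interferon-beta library. Apart from SLAMF6, these rises also did not pass without unstimulated replicate 2. CXCL10, CD80 and the rise at ISG15 passed only with all libraries or without 1 of the Pam3CSK4 libraries. Without unstimulated replicate 1, CH25H, ABCA1, KLF6 and SECTM1 did not pass, and SNX6, IRF2, ABCA1, KLF6 and SECTM1 did not without interferon-gamma replicate 2, nor, apart from IRF2, without replicate 1. SECTM1 did not pass without unstimulated replicate 2 or either interferon-beta library, and SNX6 and IRF2 did not without either LPS library.

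Type I interferon response genes moved up as a list with interferon-beta (adjusted p = 0.0287, and 0.417 with an estimated correlation), although 6 of their regions were higher and 10 lower. That balance counts the falls inside IFIT2 and IFIT3 but not the rises at the IFIT locus, which are assigned to LIPA. This balance turned with the scaling: 9 were higher and 6 lower with median centring, 10 and 10 with quantile normalization, and 10 and 6 with voom. Adjusted over the list alone, 25 were higher and 16 lower. Without unstimulated replicates 1 and 2 the counts were 2 and 7, and 0 and 1. They were 3 and 8 without either LPS library, 12 and 11 without either Pam3CSK4 library, 0 and 2 without interferon-beta replicate 1, 0 and 0 without interferon-beta replicate 2, and 3 and 5, and 2 and 4, without interferon-gamma replicates 1 and 2. Its adjusted p was 0.165 without unstimulated replicate 1 and 0.225 without interferon-beta replicate 1. Interferon-gamma response genes passed (adjusted p = 0.0119, and 0.734 with an estimated correlation), with 5 higher and 4 lower, and 19 and 10 adjusted over the list alone. Those 5 and 4 were 5 and 1, and 2 and 0, without unstimulated replicates 1 and 2, 3 and 2 without either LPS library, 12 and 6 without either Pam3CSK4 library, 0 and 0 without either interferon-beta library, and 2 and 0 without either interferon-gamma library. Interferon receptors and STATs passed with 1 region higher and 0 lower, that of IRF2, and also 1 and 0 adjusted over the list alone (adjusted p = 0.036, and 0.719 with an estimated correlation). Its adjusted p was 0.233 without unstimulated replicate 2, 0.225 without interferon-beta replicate 1 and 0.0622 with regions within 20 kb only. NF-kB and TLR inflammatory genes did not pass (adjusted p = 0.0776, and 0.862 with an estimated correlation). Median, mean and test differed in sign for the sterol, B cell and dendritic cell lists.

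**Figure D2:**
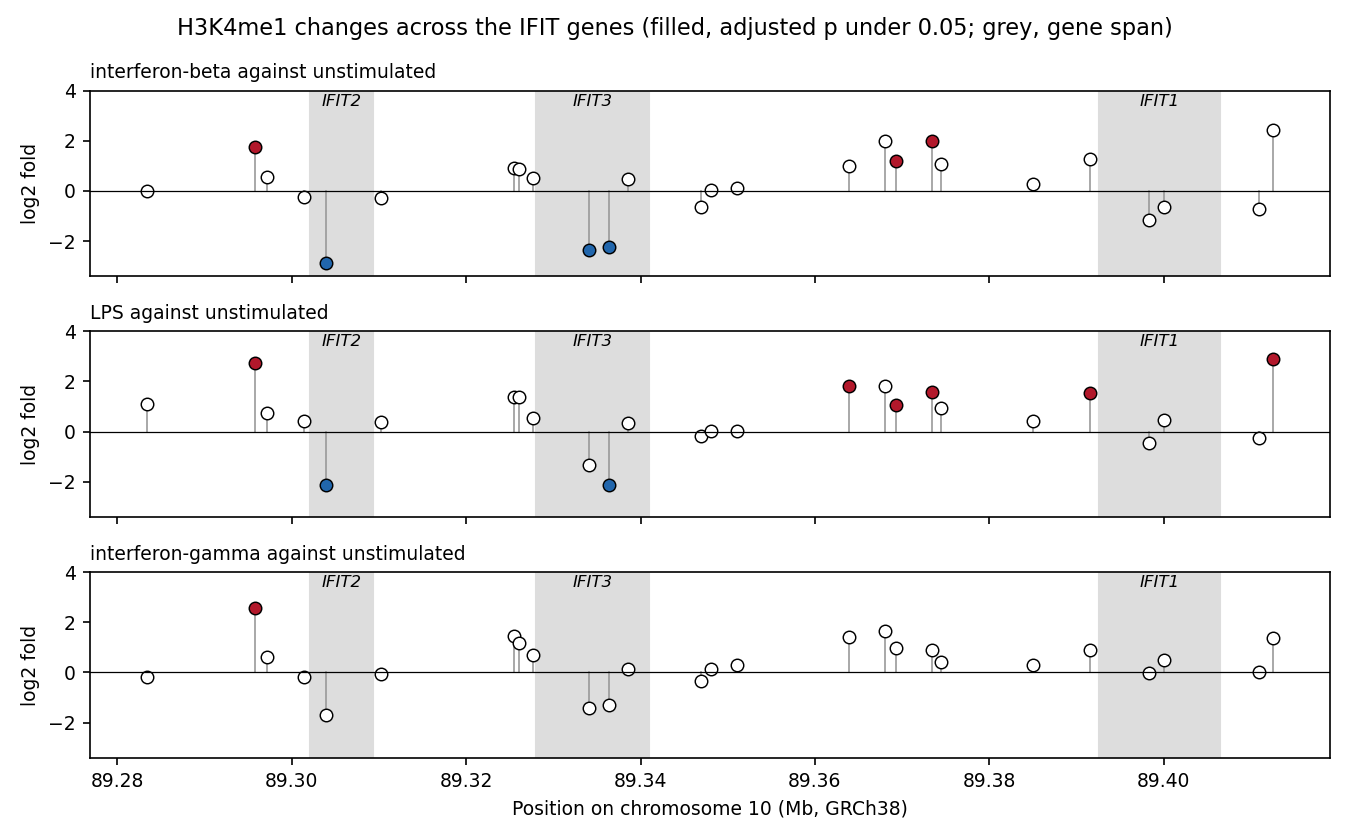
Log2 fold change against unstimulated cells (vertical axis) of each region by its position on chromosome 10 in Mb (horizontal axis) around IFIT2, IFIT3 and IFIT1, for interferon-beta, LPS and interferon-gamma, with filled symbols for adjusted p under 0.05 and grey bars for the gene spans. With interferon-beta 1 region inside IFIT2 (-2.86) and 2 of the 3 inside IFIT3 (-2.35 and -2.25) lie lowest, and regions outside these spans that passed rise by up to 1.97.

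The comparison of interferon-gamma with unstimulated cells asks what the activator of GAF does by itself. Interferon-gamma raised the mark at regions of GBP5, SOCS1, IRF1, IRF8 and JAK2. Near GBP5, regions 1.72 kb, 14.4 kb and 0.364 kb away rose by 2.39 ± 0.25 (adjusted p = 0.00122), 2.81 ± 0.41 (adjusted p = 0.00646) and 1.93 ± 0.29 (adjusted p = 0.00731). The region near SOCS1 that rose with LPS rose by 1.9 ± 0.25 (adjusted p = 0.00315). A region 9.88 kb from IRF1, the transcription factor named in the series title (chromosome 5, 132499960 to 132501346), rose by 1.16 ± 0.19 (adjusted p = 0.0122), while the region nearest to an end of IRF1 did not pass (0.34, adjusted p = 0.385). Among other regions of IRF1, chosen after their values were seen, one 3.69 kb away rose by 0.97 (adjusted p = 0.0181) and one inside the gene fell by 1.07 (adjusted p = 0.0338). A region 64.7 kb from IRF8, a myeloid partner of IRF1, rose by 1.49 ± 0.19 (adjusted p = 0.00315).

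A region 1.38 kb from JAK2, the receptor's kinase, rose by 2.60 (adjusted p = 0.024), and one inside STAT5A, a signal transducer of growth factors, by 1.76 (adjusted p = 0.0345). ACOD1 gained 2.08 (adjusted p = 0.00699), CXCL10 1.45 (adjusted p = 0.0293), ATF3 1.23 (adjusted p = 0.0423) and CH25H 1.19 (adjusted p = 0.0417). Large rises lay near SNX6 (3.70 ± 0.58, adjusted p = 0.00901), LGALS16, a galectin gene (2.81), IPO7, a nuclear import receptor (2.83), and MKX, a regulator of tendon (2.79). With 0 reads in unstimulated cells, a region near IL1R1, the receptor of interleukin-1, was at least 5.93-fold higher. Inside TMEM273, which had 1 read in unstimulated cells and 46 with interferon-gamma, the ratio of depth-scaled reads was 24.8 (95% interval 4.24 to 1000). Falls lay at PLXNA2, a semaphorin receptor (-2.22, adjusted p = 0.0143), PDZD8, a protein of membrane contact sites (-2.07, adjusted p = 0.0142), and CPQ, a peptidase (-1.96, adjusted p = 0.0398). The following regions of type I interferon genes did not pass: ISG15 (0.40, adjusted p = 0.53), MX1 (0.37, adjusted p = 0.373), IFIT1 (0.91, adjusted p = 0.302), EPSTI1 (1.62, adjusted p = 0.0638), IFIT2 (-1.68, adjusted p = 0.0662) and IFIT3 (-1.28, adjusted p = 0.0853), nor did NLRC5 (-1.62, adjusted p = 0.108). A region of the IFIT locus assigned to LIPA (chromosome 10, 89295621 to 89295922), chosen after its values were seen, rose by 2.565 (adjusted p = 0.00405). The regions of EPSTI1, IFIT2, IFIT3 and NLRC5 passed without either Pam3CSK4 library.

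In all, 625 regions passed with interferon-gamma, 498 higher and 127 lower. The split was 526 and 64 with median centring, 444 and 56 with voom and 107 and 2 without unstimulated replicate 2. The count was 109 without unstimulated replicate 2, 403 without LPS replicate 2, 1190 and 1208 without Pam3CSK4 replicates 1 and 2, 305 and 317 without interferon-beta replicates 1 and 2, and 0 and 6 without interferon-gamma replicates 1 and 2. Of 22 such regions examined by name, 0 stayed past the threshold without either interferon-gamma library, 18 without unstimulated replicate 1 and 10 without unstimulated replicate 2. The regions of SOCS1, IRF8 and SNX6, and that of GBP5 at 1.72 kb, passed without any 1 of the other 8 libraries. The regions of IRF1, ACOD1, PLXNA2 and PDZD8 and the other 2 of GBP5 did not pass without unstimulated replicate 2, and JAK2 did not without unstimulated replicate 1. CXCL10, ATF3 and CPQ did not pass without unstimulated replicate 2, LPS replicate 2 or either interferon-beta library, nor ATF3 and CPQ without LPS replicate 1. STAT5A, CH25H and IL1R1 passed only with all libraries or without 1 of the Pam3CSK4 libraries.

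Interferon-gamma response genes moved up as a list with interferon-gamma (adjusted p = 4.37e-07, and 0.417 with an estimated correlation), with 15 regions of 5 genes higher and 2 lower of 136. Adjusted over the list alone, 42 were higher and 12 lower. The counts over all regions were 12 and 1, and 4 and 0, without unstimulated replicates 1 and 2, 14 and 1 without either LPS library, 22 and 4 without Pam3CSK4 replicate 2, 12 and 0 without either interferon-beta library and 0 and 0 without either interferon-gamma library. The 131 regions of the type I list leave out the risen region of the IFIT locus that is assigned to LIPA. Of all regions outside that list 0.539% rose and 0.137% fell, so a list of its size may hold few or none. The type I list did not pass (adjusted p = 0.166, and 0.503 with an estimated correlation), with 0 regions called by limma, and 6 higher and 5 lower adjusted over the list alone. Neither did interferon receptors and STATs (adjusted p = 0.273, and 0.868 with an estimated correlation), with 3 regions higher and 2 lower, the falls at IFNGR1 (-0.78, adjusted p = 0.0468) and IRF2 (-0.69, adjusted p = 0.0495), both regions chosen after their values were seen. Without unstimulated replicates 1 and 2 these counts were 4 and 1, and 2 and 0. They were 2 and 0 without either LPS or either interferon-beta library, 6 and 3, and 7 and 3, without Pam3CSK4 replicates 1 and 2, and 0 and 0 without either interferon-gamma library. Nor did NF-kB and TLR inflammatory genes pass (0.486). Median, mean and test differed in sign for the macrophage identity, housekeeping, T and NK cell, B cell and non-blood lists.

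**Figure D3:**
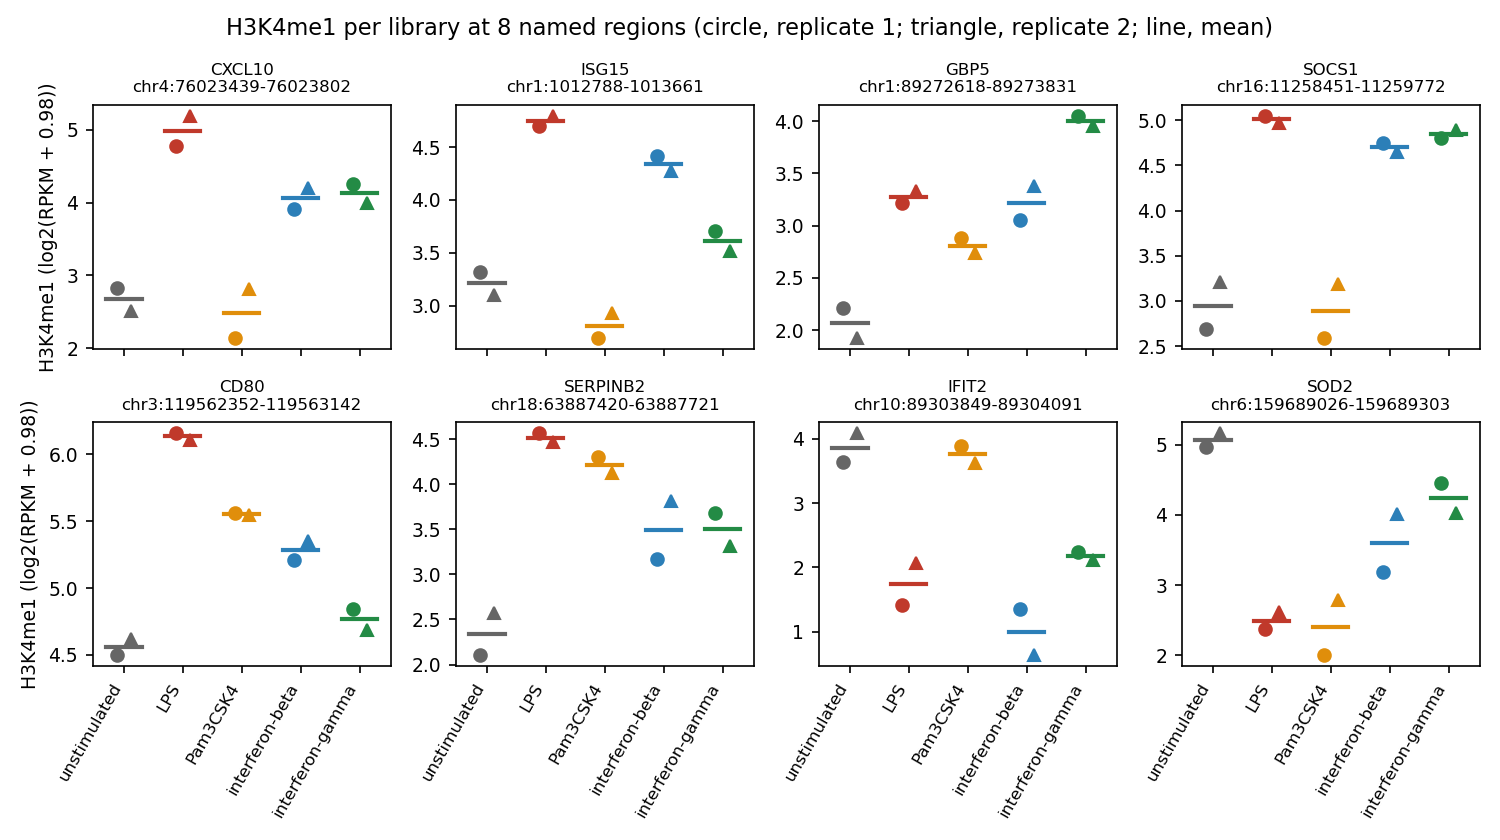
H3K4me1 in log2(RPKM + 0.98) (vertical axis) of each library by group (horizontal axis) at regions of CXCL10, ISG15, GBP5, SOCS1, CD80, SERPINB2, IFIT2 and SOD2, with circles for replicate 1, triangles for replicate 2 and lines for the group mean. At CXCL10 the LPS libraries lie at 4.77 and 5.19 and the unstimulated ones at 2.83 and 2.52.

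The direct comparison of LPS with Pam3CSK4 asks what separates TLR4 from TLR2. Regions of several interferon-induced genes carried more of the mark with LPS, and others less. The region at CXCL10 was higher by 2.50 (95% interval 1.9 to 3.10, adjusted p = 0.000841), that nearest to ISG15 by 1.94 (1.44 to 2.43, adjusted p = 0.00101), that near SOCS1 by 2.12 (1.59 to 2.64, adjusted p = 0.000951), that inside HERC6 by 2.81 (1.93 to 3.70, adjusted p = 0.00408) and that near GBP5 by 1.53 (0.99 to 2.07, adjusted p = 0.00699). The regions inside IFIT2 (-2.01, adjusted p = 0.0174), at ISG15 0.546 kb from the gene (-1.69, adjusted p = 0.0111), inside SECTM1 (-1.77, adjusted p = 0.00156) and inside WARS1 (-1.45, adjusted p = 0.00381) were lower with LPS. A difference was not detected at SERPINB2 (0.30, -0.29 to 0.90, adjusted p = 0.641) or SOD2 (0.09, -0.60 to 0.79, adjusted p = 0.922), and CD80 (0.58, adjusted p = 0.0634) and IFIT1 (1.40, adjusted p = 0.0571) did not pass, nor did the regions nearest to GBP5 (0.47, adjusted p = 0.455) and MX1 (0.19, adjusted p = 0.609). Without LPS replicate 2 the adjusted p was 0.0653 at CXCL10, nearest to ISG15 and at SECTM1, 0.0618 at SOCS1, 0.144 at HERC6, GBP5 and IFIT2, 0.23 at ISG15 0.546 kb from the gene and 0.086 at WARS1. That of IFIT2 was 0.085 without LPS replicate 1.

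Large differences in favour of LPS lay inside RUFY4, a regulator of autophagy (3.28 ± 0.29, adjusted p = 0.000322), and near GMPR, an enzyme of purine metabolism (3.32, adjusted p = 0.000793). Another lay inside the adaptor gene SH3KBP1 (3.35, adjusted p = 0.00338). With 0 reads in Pam3CSK4 cells, the regions of JMJD1C and FASLG were at least 21.0-fold and at least 13.3-fold higher. Near IFITM1, which blocks viral entry, the mark was lower with LPS (-2.41, adjusted p = 0.0021), as it was inside MME, a peptidase gene (-2.30, adjusted p = 0.0112), and near the GTPase gene RALB (-2.25, adjusted p = 0.00899). Of these 8 regions, RUFY4 alone passed without LPS replicate 2, and MME did not pass without Pam3CSK4 replicate 2. In all, 1606 regions passed, 1405 higher and 201 lower with LPS. With voom 764 were higher and 589 lower, and without LPS replicate 1 846 and 429. The count was 9 without LPS replicate 2, 3267 without Pam3CSK4 replicate 1, 942 and 989 without interferon-beta replicates 1 and 2, and 802 and 782 without interferon-gamma replicates 1 and 2. Type I interferon response genes were higher with LPS as a list (adjusted p = 0.00721, and 0.417 with an estimated correlation), with 14 regions higher and 9 lower, and 32 and 16 adjusted over the list alone. Those counts were 5 and 3 without LPS replicate 1, 0 and 0 without LPS replicate 2, 23 and 7 without Pam3CSK4 replicate 1, and 12 and 4 without either interferon-gamma library. Interferon-gamma response genes did not pass (adjusted p = 0.249, and 0.868 with an estimated correlation), with 9 regions higher and 10 lower. These counts were 5 and 6 without LPS replicate 1, 0 and 0 without LPS replicate 2, 8 and 6 without Pam3CSK4 replicate 2, 6 and 6, and 7 and 6, without interferon-beta replicates 1 and 2, and 4 and 4 without either interferon-gamma library. The NF-kB list did not pass (adjusted p = 0.537), and median, mean and test differed in sign for the MHC class I, housekeeping and B cell lists.

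The direct comparison of interferon-gamma with interferon-beta asks what separates the activator of GAF from the activator of ISGF3. No single region passed: limma called 0, with 4366 regions at an unadjusted p under 0.05 and a smallest adjusted p of 0.128. Library weights called 97, a fit of only the 2 groups 133 and voom 148, and the count was 0 without any 1 of the 10 libraries. The region nearest to ISG15 differed by -0.73 (95% interval -1.23 to -0.23, adjusted p = 0.862), that 0.546 kb from ISG15 by 1.51 (0.86 to 2.16, adjusted p = 0.342), that nearest to GBP5 by 0.79 (0.17 to 1.41, adjusted p = 0.967) and that inside HERC6 by -1.63 (-2.52 to -0.74, adjusted p = 0.693). CXCL10 differed by 0.07 (-0.53 to 0.67) and SOCS1 by 0.15 (-0.38 to 0.67). As a list, interferon-gamma response genes were higher with interferon-gamma (adjusted p = 0.000512, and 0.59 with an estimated correlation), with 1 region higher and 0 lower adjusted over the list alone. The adjusted p was 0.0584 without interferon-gamma replicate 1. The type I list did not pass (adjusted p = 0.613, and 0.868 with an estimated correlation). Median, mean and test differed in sign for the housekeeping list.

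The direct comparison of LPS with interferon-beta asks what LPS does beyond type I interferon. Higher with LPS were regions inside SLCO3A1, an organic anion carrier (2.14 ± 0.23, adjusted p = 0.00703), and DNAAF11, an assembly factor of cilia (2.08, adjusted p = 0.0397). Regions near the calcium channel gene ITPR1 (1.87), inside the G protein gene GNA12 (1.85), inside IL19, a cytokine of the interleukin-10 family (1.74), inside ITGB8, an integrin that activates TGF-beta (1.69), and near RIPK2, a kinase of NOD receptors (1.65), were also higher, each with adjusted p = 0.0265. In all, 8 regions passed, 8 higher and 0 lower by limma, with 7010 regions at an unadjusted p under 0.05, and 2198 passed with voom. The count was 0 without either LPS or either interferon-beta library, 19 and 20 without unstimulated replicates 1 and 2, 48 and 57 without Pam3CSK4 replicates 1 and 2, and 1 without either interferon-gamma library. CD80 (0.85, adjusted p = 0.0909) and CXCL10 (0.92, adjusted p = 0.392) did not pass. As lists, NF-kB and TLR inflammatory genes (adjusted p = 4.17e-05, and 0.503 with an estimated correlation) and type I interferon response genes (adjusted p = 0.0367, and 0.417 with an estimated correlation) were higher with LPS. The NF-kB list had 8 higher and 2 lower adjusted over the list alone, and its adjusted p was 0.301 without LPS replicate 2. The adjusted p of the type I list, with 0 and 0 adjusted over the list alone, was 0.096 and 0.139 without LPS replicates 1 and 2 and 0.0901 and 0.0928 without interferon-beta replicates 1 and 2. Median, mean and test differed in sign for the macrophage identity, neutrophil, and platelet and erythroid lists.

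De novo regions, as defined for this table, numbered 1659 with LPS, 59 with Pam3CSK4, 236 with interferon-beta and 307 with interferon-gamma. They were 52.6%, 47.6%, 62.9% and 61.7% of the regions that rose. Of the 92539 tested regions 46269 lay above the unstimulated median, and 1483, 65, 139 and 190 of the rises lay among these. With LPS and Pam3CSK4 the de novo share was thus near the share of all regions under that median. The same 2 unstimulated libraries set both the baseline and the fold change, which favours rises from a low baseline. Most de novo regions had some reads in unstimulated cells: 48, 3, 6 and 8 of them had none, as in the regions of JMJD1C and KDM4C with LPS. Of the 424 regions that were de novo with an interferon, 342 were also de novo with LPS, 119 were de novo with both interferons, and 8 with all 4 stimuli. The LPS number was 113 without LPS replicate 2, 1015 without LPS replicate 1, 771 without unstimulated replicate 2 and 2493 without either Pam3CSK4 library. The interferon-beta number was 4 and 2 without interferon-beta replicates 1 and 2, 54 without unstimulated replicate 2, 360 without unstimulated replicate 1, 138 and 128 without LPS replicates 1 and 2, 117 and 105 without interferon-gamma replicates 1 and 2, and 460 and 459 without Pam3CSK4 replicates 1 and 2. The interferon-gamma number was 0 and 3 without interferon-gamma replicates 1 and 2, 84 without unstimulated replicate 2, 202 and 177 without LPS replicates 1 and 2, 171 and 174 without interferon-beta replicates 1 and 2, and 561 and 562 without Pam3CSK4 replicates 1 and 2. The Pam3CSK4 number was 226 and 6 without unstimulated replicates 1 and 2, 320 without Pam3CSK4 replicate 1, 7 and 6 without LPS replicates 1 and 2, 16 and 18 without interferon-beta replicates 1 and 2, and 8 without either interferon-gamma library.

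Regions that rose lay away from gene ends more often than other regions, by Fisher's exact test. That test takes every region as independent, though neighbouring regions are not, so its p-values for rises and falls may be too small. They do not measure the spread between the 2 libraries of a group. Regions were not matched on signal or width. With LPS 91.5% of the risen regions were over 1 kb from any gene end, against 80.7% of other regions (odds ratio 2.59, adjusted p = 1.02e-61). The shares were 90.3% against 81.1% with Pam3CSK4 (adjusted p = 0.0105), 89.1% against 81.0% with interferon-beta (adjusted p = 6.11e-05) and 90.4% against 81.0% with interferon-gamma (adjusted p = 3.95e-08). Beyond 5 kb the difference passed with LPS (66.4% against 56.9%, adjusted p = 6.06e-26) and interferon-gamma (66.9%, adjusted p = 2.46e-05) and did not with Pam3CSK4 (63.7%, adjusted p = 0.148) or interferon-beta (61.3%, adjusted p = 0.133). Of the regions that fell, 80.5% lay over 1 kb from gene ends with LPS (exact p = 0.657), 75.6% with Pam3CSK4 (p = 0.118), 88.1% with interferon-beta (p = 0.0362) and 85.8% with interferon-gamma (p = 0.212). For falls the share with LPS was 76.7% (exact p = 0.00142) without unstimulated replicate 1, 66.5% (exact p = 8.05e-44) without LPS replicate 1 and 72.2% (exact p = 9.99e-49) with voom. It was 84.1% (exact p = 0.000905) with Pam3CSK4 without its replicate 1 and 71.8% (exact p = 0.00543) with interferon-gamma without unstimulated replicate 1. The p of 0.0362 for interferon-beta stayed under 0.05 in no alternative. It was 0.331 with median centring, 0.0826 with quantile normalization, 0.0618 with a constant of 1, 0.108 with the replicate block, 0.076 with a robust prior and 0.296 with voom. It was 0.929 and 1 without unstimulated replicates 1 and 2, 0.458 without either LPS library, 0.136 and 0.0721 without Pam3CSK4 replicates 1 and 2, 1 without either interferon-beta library, and 0.135 and 0.15 without interferon-gamma replicates 1 and 2. The exact p for interferon-beta at 1 kb was 0.178 without unstimulated replicate 2 and 0.238 and 1 without interferon-beta replicates 1 and 2, and that for interferon-gamma was 0.602 without interferon-gamma replicate 2. For Pam3CSK4 the exact p was 1 without unstimulated replicate 2, 0.484 and 0.14 without LPS replicates 1 and 2, 0.316 without Pam3CSK4 replicate 2, 0.637 and 0.498 without interferon-beta replicates 1 and 2, and 0.0912 without either interferon-gamma library.

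Rises were shared between stimuli. Of the 375 regions that rose with interferon-beta, 368 rose with LPS, where independent lists would share 12.8. LPS shared 358 of the 498 rises with interferon-gamma (independent lists 17.0) and 93 of the 124 with Pam3CSK4 (independent lists 4.23). The interferons shared 175 rises (independent lists 2.02), and Pam3CSK4 shared 22 with interferon-beta (0.503) and 17 with interferon-gamma (0.667). Against simulated unchanged groups that share the unstimulated libraries, the covariance of the fold changes was larger by 0.152 for LPS and interferon-beta, 0.128 for LPS and interferon-gamma, 0.105 for the interferons, 0.0958 for LPS and Pam3CSK4, 0.0683 for Pam3CSK4 and interferon-beta and 0.0513 for Pam3CSK4 and interferon-gamma. The correlation was 0.738, 0.66, 0.708, 0.517, 0.525 and 0.462 for these pairs in that order, against 0.499 to 0.500 in the simulations, so for the 3 pairs with Pam3CSK4 it lay near or under the simulated value. Simulated unchanged groups, which leave out the effects, shared 0 to 0.05 rises on average. A split of the controls would leave 1 unstimulated library for each side, so part of the excess overlap may come from the shared controls. Regions that rose with all 4 stimuli numbered 10, among them regions of P2RX7, an ATP receptor that triggers the inflammasome, of TMEM273 and of SMCHD1, a chromatin repressor, chosen after their values were seen.

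In all, 619 regions rose with 2 or more stimuli. The number was 125 without unstimulated replicate 2, 395 and 180 without LPS replicates 1 and 2, 1239 and 1048 without Pam3CSK4 replicates 1 and 2, 219 and 221 without interferon-beta replicates 1 and 2, and 183 and 166 without interferon-gamma replicates 1 and 2. Of the 698 regions that rose with an interferon, 552 (79.1%) also rose with LPS, and that share was 29.1% without LPS replicate 2.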

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

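The tests of each stimulated library by itself and of LPS replicate 1 in regions chosen without it, and the thinning of the libraries as an alternative, were chosen after the results or the data were seen.

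A signal appeared in data that the comparisons leave out. The 1 region past the threshold on the alternate contig GL000251v2 of chromosome 6 rose by 1.67 with LPS (adjusted p = 0.0349). It differed by 1.39 with Pam3CSK4 (adjusted p = 0.168), 0.70 with interferon-beta (adjusted p = 0.543) and 0.63 with interferon-gamma (adjusted p = 0.598). These came from a fit that included the left-out regions, and no explanation was tested.

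LPS changed 4168 regions and interferon-gamma, the next stimulus, 625, and deeper LPS libraries and a set of regions drawn from LPS peaks are each excluded as the whole cause, since LPS called 13.6 times as many regions as the next stimulus after thinning and 7.86 times as many (2469 against 314) among regions above the unstimulated median. A single deviating LPS library was tested with each library by itself against both unstimulated ones, 1 spread for all and all thinned. LPS replicates 1 and 2 called 91 and 873 regions and any other library at most 1 (medians of 5 draws, ratio 91). This argues against a single library as the whole cause, though replicate 2 holds most of the excess. It does not exclude it, since the LPS replicates differed more than those of other groups. Their dispersion was 0.0497, against 0.0178 to 0.0255, so a lone LPS library may pass a shared spread more easily. The test first planned, 299 for LPS against 403 for interferon-gamma without LPS replicate 2, went the other way but set 1 library against 2 and decides nothing (interferon-gamma called 0 and 6 without its own replicates 1 and 2), and the LPS count was 1411 without unstimulated replicate 2 and 6652 and 6718 without Pam3CSK4 replicates 1 and 2. In regions higher in LPS replicate 2 against 1 unstimulated library, replicate 1 lay above the other unstimulated library in 91.8% (2317 regions) and 98.5% (919 regions). These shares were at least 39.0 points over those of uncalled regions matched on the first library. Most regions gained in replicate 2 thus shifted the same way in replicate 1. The test compares directions over the whole set, so gains in replicate 2 alone at some regions are not excluded. A broader action of TLR4, which signals through both inflammatory and interferon-inducing adaptors, may also contribute and stays open, with replicates of unknown origin.

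Pam3CSK4 changed 255 regions, the fewest of the 4 stimuli, and its libraries are the shallowest of the 4. Fewer reads within the given regions do not account for the whole difference. With all libraries thinned alike the smaller of the interferon counts was 111 and the Pam3CSK4 count 11, a ratio of 10.1. How the regions were defined is not known, so shallow Pam3CSK4 libraries may also have added few regions to the set. Thinning cannot test that. Among regions above the unstimulated median, 169 passed with Pam3CSK4, 270 with interferon-beta and 314 with interferon-gamma. The full Pam3CSK4 count was 9 without unstimulated replicate 2 and 2328 without Pam3CSK4 replicate 1. It was 434 without unstimulated replicate 1, 452 without Pam3CSK4 replicate 2, 23 and 21 without LPS replicates 1 and 2, 50 and 53 without interferon-beta replicates 1 and 2, and 23 and 24 without interferon-gamma replicates 1 and 2. Beyond sampling noise the dispersion of the Pam3CSK4 libraries was 0.0178, near that of interferon-beta (0.0183) and interferon-gamma (0.0185). It was 0.0255 for unstimulated cells and 0.0497 for LPS. These values cover only regions well read in both libraries, 39774 for Pam3CSK4 and 77067 for LPS. The correlation between replicates, which also holds sampling noise, was lowest for Pam3CSK4 (r = 0.843). A wide spread between these libraries in the values tested is therefore not excluded, and a narrower action of TLR2 stays open.

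No region differed between the interferons by limma, with 4366 regions at an unadjusted p under 0.05, while 97 passed with library weights, 133 with only the 2 groups in the fit and 148 with voom. Too little power may explain this. Simulated data had these depths and this spread, with 200 regions changed between interferon-gamma and interferon-beta. They gave back 0% of 2-fold changes and 77% of 4-fold changes. Differences of 2-fold between interferon-gamma and interferon-beta stay open.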

How the results depend on the processing

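Thinning to equal depth and voom were chosen after the data were seen. The other alternatives were planned.

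Of the 156 regions examined by name, 0 of 3097 values under alternatives passed in the opposite direction, and 598 were no longer past the threshold, 399 of them with 1 library left out. Median centring, quantile normalization, a constant of 1, leaving out the lowest 25% of regions and a robust prior kept the number of regions called within 1.5 times, from 3808 to 4650 for LPS, 217 to 256 for Pam3CSK4, 505 to 689 for interferon-beta and 590 to 837 for interferon-gamma. The exception is LPS against interferon-beta, with 16 (quantile) and 14 (lowest 25% left out) in place of 8. The cause was not tested. The scalings moved the median log2 fold by at most 0.08. The split of higher and lower moved for interferon-beta with median centring (461 and 85, against 375 and 134), for interferon-gamma with median centring (526 and 64, against 498 and 127) and for Pam3CSK4 with quantile normalization (147 higher of 248, against 124 of 255).

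Leaving out 1 library assumes that the lone library of a group varies like the other groups. The order of the stimuli changed in several of these fits. LPS called fewer regions than both interferons without LPS replicate 2, and Pam3CSK4 called more than both without Pam3CSK4 replicate 1. Interferon-beta called more than interferon-gamma without unstimulated replicate 1. Pam3CSK4 also called more than an interferon that had lost 1 library. The counts ran from 299 to 6718 for LPS, 9 to 2328 for Pam3CSK4, 4 to 1142 for interferon-beta, 0 to 1208 for interferon-gamma, 9 to 3267 for LPS against Pam3CSK4, 0 to 57 for LPS against interferon-beta, and stayed at 0 for interferon-gamma against interferon-beta. De novo regions ran from 113 to 2493 with LPS, 6 to 320 with Pam3CSK4, 2 to 460 with interferon-beta and 0 to 562 with interferon-gamma. Distal shares ran from 89.2% to 91.8% with LPS, 86.2% to 100% with Pam3CSK4, 87.7% to 100% with interferon-beta and 88.2% to 100% with interferon-gamma, which has no value without its replicate 1. The overlap of 2 or more stimuli ran from 125 to 1239, and 11 to 20 list tests passed.

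With only the 2 groups compared, which leaves fewer libraries to estimate the spread, the counts were 0 for Pam3CSK4 (de novo 0, no distal share), 40 for interferon-beta (de novo 21), 412 for LPS against Pam3CSK4, 133 for interferon-gamma against interferon-beta and 373 for LPS against interferon-beta. De novo regions with interferon-gamma were 202 and the overlap 227. Library weights gave 15 for Pam3CSK4 (de novo 5, distal 100%), 987 for interferon-beta (de novo 395), 1233 for interferon-gamma (de novo 542), 591 for LPS against Pam3CSK4, 97 for interferon-gamma against interferon-beta and 141 for LPS against interferon-beta. With voom the counts were 9292 for LPS, 9 for Pam3CSK4 (de novo 4, distal 100%), 148 for interferon-gamma against interferon-beta and 2198 for LPS against interferon-beta. The split then moved to 4866 higher and 4426 lower for LPS (from 3157 and 1011), 764 and 589 for LPS against Pam3CSK4 (from 1405 and 201) and 1493 and 705 for LPS against interferon-beta (from 8 and 0). The cause was not tested for weights, voom or the fit of only the 2 groups, where some counts fell and others rose.

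Thinning, which leaves fewer reads, gave 1959 for LPS (de novo 752), 11 for Pam3CSK4 (de novo 4, distal 87.5%), 111 for interferon-beta (de novo 53), 144 for interferon-gamma (de novo 73), 373 for LPS against Pam3CSK4, 0 for LPS against interferon-beta and an overlap of 134. With a baseline in the lowest 25%, a stricter definition, de novo regions were 1002, 31, 137 and 186 for LPS, Pam3CSK4, interferon-beta and interferon-gamma. Beyond 5 kb the distal share did not pass with Pam3CSK4 (63.7%) or interferon-beta (61.3%). With an estimated correlation 0 list tests passed, and with regions within 20 kb 11, against 14.

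The replicate numbers showed no clear pairing of the libraries. The differences between replicates correlate across groups from -0.192 to 0.124. Sampling noise in these differences may hide a shared effect, so pairing is not excluded. As a block the replicate numbers gave 3703, 119 (de novo 29), 390 and 450 regions for LPS, Pam3CSK4, interferon-beta and interferon-gamma, and 1371, 0 and 8 for the 3 direct comparisons. The block with a GC correction and the motif tests were not run, for lack of a genome sequence.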

Other observations

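The tests of position around genes, the genes with many gained regions and the regions of the IFIT locus were chosen after the results were seen.

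On chromosome 6 the table has 0 regions from 30 to 33 Mb, against 54 from 27 to 30 Mb and 198 from 33 to 36 Mb.

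Rises gathered at some genes. With LPS, 35 of 14562 genes held more risen regions than their number of regions gives by chance (hypergeometric test). ITGB8 had 16 of 35 (adjusted p = 1.04e-10), the B cell chemokine gene CXCL13 9 of 9 (adjusted p = 4.51e-10), the kinase gene LYN 14 of 40 (adjusted p = 8.24e-08), IDO2 10 of 19 (adjusted p = 3.56e-07), RIPK2 9 of 23 (adjusted p = 6.82e-05), GBP5 6 of 9 (adjusted p = 0.00016), the chemokine gene CCL8 4 of 5 (adjusted p = 0.00479) and IL1RN, the antagonist of interleukin-1, 6 of 16 (adjusted p = 0.00619). With interferon-gamma 13 genes passed, among them GBP5 with 6 of 9 (adjusted p = 2.84e-08), SOCS1 with 4 of 7 (adjusted p = 0.000139) and NOS2, the inducible nitric oxide synthase, with 3 of 6 (adjusted p = 0.00557). With interferon-beta 13 passed, among them LYN with 6 of 40 (adjusted p = 8.9e-05) and NOS2 with 3 of 6 (adjusted p = 0.00212), and with Pam3CSK4 0 did. Neighbouring regions are not independent, so these p-values are too small by an amount that was not tested. A region of NOS2 rose by 2.82 with LPS (adjusted p = 8.08e-05), 2.13 with interferon-beta (adjusted p = 0.00356) and 1.94 with interferon-gamma (adjusted p = 0.00448).

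At the IFIT locus, 3 regions outside IFIT2 and IFIT3 rose with interferon-beta while 1 region inside IFIT2 and 2 inside IFIT3 fell. Another inside IFIT3 did not pass (0.45, adjusted p = 0.802), nor did the other regions of the locus. The region 89295621 to 89295922 of chromosome 10 rose by 1.76 (adjusted p = 0.0327), 89368983 to 89369705 by 1.20 (adjusted p = 0.0298) and 89373366 to 89373611 by 1.97 (adjusted p = 0.0168). With LPS the same 3 regions rose by 2.76 (adjusted p = 0.00053), 1.05 (adjusted p = 0.0172) and 1.60 (adjusted p = 0.0135), and 1 region inside IFIT2 and 1 inside IFIT3 fell by 2.11 (adjusted p = 0.00637) and 2.12 (adjusted p = 0.00173), while another inside IFIT3 did not pass (-1.33, adjusted p = 0.0685). With interferon-gamma the region 89295621 to 89295922 rose by 2.565 (adjusted p = 0.00405). The regions 89368983 to 89369705 (0.97, adjusted p = 0.0743) and 89373366 to 89373611 (0.91, adjusted p = 0.278) did not pass with interferon-gamma. A hypothesis is that falls sit at the genes, where strong transcription may replace H3K4me1, and rises away from them. Over the type I interferon list the regions are too few to decide it: with LPS 11 of 12 lower and 17 of 22 higher regions lay inside or within 1 kb of the gene, with interferon-beta 10 of 10 and 5 of 6, and the smaller exact p was 0.375. Had the regions been split by position as far as these numbers allow, the exact p would still be 0.0691 with LPS and 0.375 with interferon-beta. The rises at the IFIT locus given above are assigned to LIPA and so are left out of the counts for this list. Over all regions, 65.3% of lower and 58.2% of higher ones lay there with LPS (exact p = 5.8e-05), 63.4% and 47.6% with Pam3CSK4 (exact p = 0.0121), 63.4% and 55.5% with interferon-beta (exact p = 0.127) and 61.4% and 51.8% with interferon-gamma (exact p = 0.0583). These exact tests also take neighbouring regions as independent, so their p-values may be too small. The hypothesis stays open.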
